A study of Mus musculus with 20 samples.

How the data were processed

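RNA was measured by sequencing of plantaris tendons from mice whose Igf1r alleles carry flox sites, with or without the tamoxifen-activated recombinase CreERT2 placed at Scx, the gene of a transcription factor of tenocytes, the fibroblasts of tendon. The labels give 20 libraries in 5 groups of 4. WT day 0 mice lacked the recombinase and had neither tamoxifen nor a growth stimulus. WT and KO mice at day 7 and day 14 had tamoxifen and the growth stimulus. WT stands for mice without CreERT2 and KO for mice with CreERT2 on both alleles, as the labels name them. No KO group without the growth stimulus was analysed here, so each KO time course starts from WT day 0. Groups and replicate numbers came from the sample titles. The labels do not say that replicates are separate animals, so p-values measure the spread between these libraries, which may be technical.

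The authors deposited raw counts per gene, which are whole numbers for 24885 genes, with no gene whose counts over the 20 libraries sum to less than 21. Reads were checked with FastQC and aligned with STAR to mm10, per the submitters' processing notes. The versions, the counting tool, the gene annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and of a gene on the opposite strand cannot be told apart, and genes that share sequence with a pseudogene or a close relative are uncertain. The authors also deposited a table of their own edgeR comparisons over 13266 genes, with log2 fold changes and average log2 CPM per the file headers. The p-values and false discovery rates in that table are the authors' own, per the file headers. Its counts of genes, the directions of its calls and its log2 fold changes were set beside those computed here, and it entered no test.

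Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's filterByExpr with its default settings, which left 18918 genes, and library sizes were scaled with TMM factors. A quasi-likelihood model with 1 mean per group was fitted to all 20 libraries with robust dispersions, so that every comparison shares 1 estimate of the spread. Comparisons were tested with edgeR's quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The comparisons were WT day 7 and WT day 14 against WT day 0, WT day 14 against WT day 7, each KO day against WT day 0, KO day 14 against KO day 7, KO against WT at day 7 and at day 14, their mean, and the interaction of genotype and day, which is the difference between the KO effects at both days. CPM is edgeR's count scaled by library size, after TMM scaling. Log-scale CPM used a prior count of 2. Single genes were also compared with two-sided exact permutation tests, for which 4 against 4 libraries give 70 arrangements and a smallest p of 0.0286.

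The design, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The 38 lists hold genes of IGF and FoxO signalling, of tendon cells, collagens and other matrix, of growth factor pathways, of the cell cycle, translation, secretion, metabolism and inflammation, and markers of other cell types a tendon sample could hold. List members were counted at the adjusted p over all genes and again adjusted over the list alone. Lists were tested in 7 comparisons with camera from limma, with a preset correlation of 0.01 between genes. Camera with an estimated correlation was the alternative. The named genes were Igf1r and Scx in every comparison. In each of the WT comparisons and each comparison of KO with WT, they further included up to 8 genes that rose and 8 that fell with the largest change, a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out predicted and unnamed genes. For each list, up to 4 members past the threshold with the smallest p could be named, or up to 2 where none passed. Up to 10 genes could be named for the interaction if any passed. A list member could be named again in another comparison. Bop1 and the genes near Scx were singled out after their values were seen.

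The alternatives were RLE and upper-quartile scaling, no filter on low counts, a stricter filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, a fit to the compared groups alone, the replicate number as a block, a muscle score as a covariate, and leaving out each library in turn. The replicate numbers were checked for pairing and the libraries for duplicates. No duplicate was found, since every pair of libraries within a group differed by more than sampling noise (smallest chi-square per degree of freedom 14.2). Folds against a group without counts used a floor of 3 counts over the group, and ratios against 1 to 3 counts have a 95% counting interval. These cover counting error only, as reads without molecular identifiers are not independent molecules.

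Coordinates are from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 also names. Of the tested genes, 99.96% were matched to it by identifier. The tests were checked on simulated counts drawn from the real means and library sizes. In the simulated comparison of KO with WT at day 7, over 18602 genes, 49.3% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, and 5 of 162 calls were false. In the simulated interaction, over 18560 genes, 20.9%, 68.7% and 95.5% were recovered at these folds. With 1 list shifted 1.5-fold in a simulation of KO against WT at day 7, camera called that list and 0 of the 37 others. The simulated genes were drawn independently of each other. This does not show how camera's preset correlation performs where members of a list vary together. Nor does it show the rate of false calls where many genes vary together between libraries. All changed genes had an average log2 CPM above 1, so recovery of genes with fewer counts was not checked.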

Results

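Gene expression was profiled in mouse plantaris tendons, to follow tendon growth under a growth stimulus and to ask how it differs when the IGF1 receptor gene Igf1r is targeted for deletion in tenocytes. The 20 libraries comprised 4 each of WT day 0, WT day 7, KO day 7, WT day 14 and KO day 14. Library depth ranged from 32.3 to 63.5 M counts, and 18918 genes were tested. The first principal component held 51.5% of the variance and the second 12%.

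Igf1r (ENSMUSG00000005533, chromosome 7, 67952827 to 68233668, plus strand, GRCm38), the targeted gene, was read in every library. The WT day 0 libraries had 63.1, 70.9, 60.5 and 56.4 CPM in the order of their replicate numbers. The WT day 7 libraries had 46.1, 50.5, 49.3 and 50.8 CPM and the KO day 7 libraries 55.0, 49.3, 49.0 and 52.0 CPM. The WT day 14 libraries had 44.6, 40.6, 47.6 and 48.7 CPM and the KO day 14 libraries 49.8, 52.3, 60.4 and 49.8 CPM. At day 7 the means were 49.2 ± 2.17 CPM in WT and 51.3 ± 2.81 in KO (SD, n = 4; two-sided exact permutation p = 0.314). At day 14 they were 45.3 ± 3.63 in WT and 53.1 ± 5.0 in KO (SD, n = 4; exact permutation p = 0.0286; edgeR adjusted p = 0.162). The Igf1r count was thus not lower in the libraries labelled KO. A count over the whole gene does not show whether an exon between the flox sites is missing, so it checks neither the deletion nor the labels.

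Scx (ENSMUSG00000034161, chromosome 15, 76457452 to 76459458, plus strand), which carries the recombinase in KO mice, separated the genotypes in every library. Its level was 50.5 ± 5.52 CPM in WT and 736 ± 281 CPM in KO at day 7, and 114 ± 30.7 in WT and 1249 ± 513 in KO at day 14 (SD, n = 4; exact permutation p = 0.0286 at each day, the smallest this design allows). Bop1 (ENSMUSG00000022557, chromosome 15, 76452989 to 76477277, minus strand), a ribosome assembly factor whose intron 3 holds all of Scx, rose with it. Bop1 stood at 74.6 ± 9.68 CPM in WT and 260 ± 60.7 in KO at day 7, and at 71.4 ± 13.5 and 378 ± 140 at day 14. Because strand use is not given, the counts of this overlapping pair are uncertain.

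**Figure D1:**
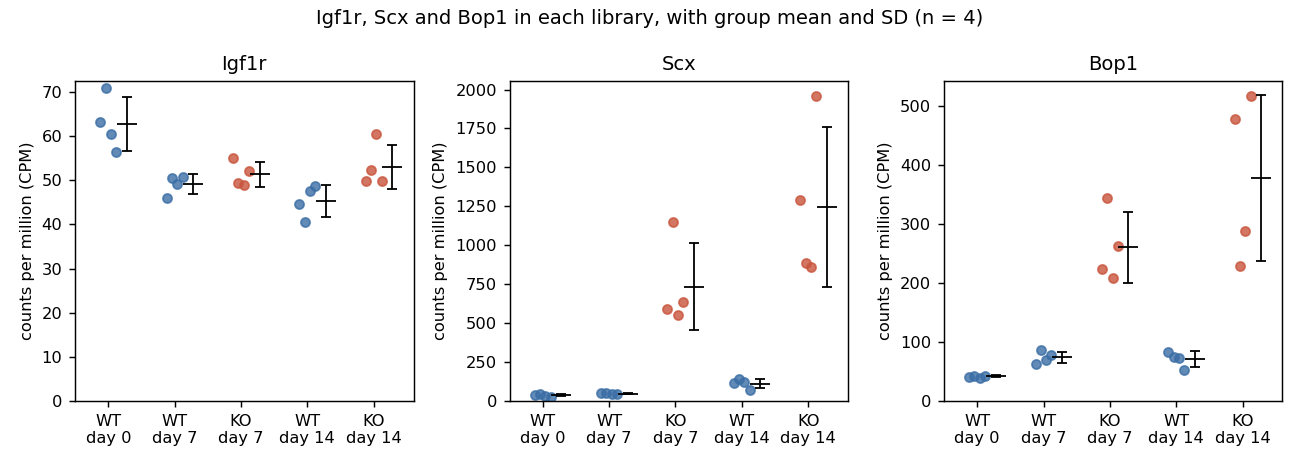
CPM of Igf1r, Scx and Bop1 in each library (points, WT blue and KO red), with the group mean and SD (bars, n = 4). The KO libraries lie above all WT libraries for Scx and Bop1, while Igf1r in KO lies within or above the range of WT at the same day.

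**Figure D2:**
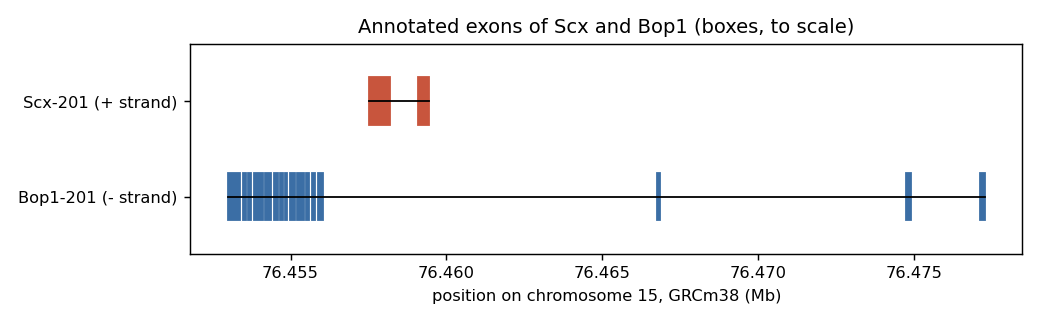
Exons of 1 annotated transcript of Scx and of Bop1 on chromosome 15 of GRCm38 (boxes, to scale; x axis in Mb). Scx lies on the opposite strand within intron 3 of Bop1, and the annotated exons share 0 bases.

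The comparison of WT day 7 with WT day 0 asks how tendon changes within a week of the growth stimulus. The mice at day 7 and day 14 also had tamoxifen and those at day 0 had none, so stimulus and tamoxifen are not separated in any comparison with day 0. Camera with its preset correlation placed 12 lists higher, among them cell cycle genes, collagens and macrophage markers, and 9 lower, among them muscle fibre, adipocyte and mitochondrial genes. All 21 of these calls were lost with an estimated correlation. Cthrc1, a secreted matrix glycoprotein, rose by 7.43 ± 0.23 on the log2 scale (SE, n = 4 per group), and Adam12, a membrane protease, Lrrc15 and C1qtnf3 by 6.79, 6.52 and 6.84. The chemokine gene Cxcl5 rose by 8.04 ± 1.15, the macrophage lectin Chil3 by 7.22, and Mymk and Chrng, of fusing myoblasts and immature muscle endplates, by 6.96 and 6.58. Odf3l2 changed by -9.36, the muscle calcium buffer Pvalb by -8.68 and Lrrc38 by -8.93. Mrgprg had 1 count at day 7 and 3861 at day 0, a ratio of 4990 (95% counting interval 895 to 197200), and the keratin Krt2 was at least 990-fold lower, with 0 counts against 2298. In all, 6110 genes rose and 6023 fell (edgeR, Benjamini-Hochberg adjusted p below 0.05), of which 2666 and 3188 changed at least 2-fold. With the muscle score as a covariate 6839 genes passed.

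All 44 cell cycle genes rose, also adjusted over the list alone, with a median log2 change of 3.26 (camera adjusted p = 3.33e-33; adjusted p = 0.189 with an estimated correlation). The mitotic kinase Cdk1 rose by 4.43, the cyclin Ccnb2 by 4.10 and Rrm2, which makes deoxynucleotides, by 3.31. Of 20 fibrillar and associated collagens 15 rose, 3 fell and 2 did not pass, with 15 and 3 adjusted over the list alone (camera adjusted p = 1.25e-05; adjusted p = 0.332 with an estimated correlation). Col3a1 rose by 2.56, Col8a1 by 3.77 and Col5a2 by 2.10. Of 26 collagen processing enzymes 21 rose and 3 fell, again 21 and 3 adjusted over the list alone (camera adjusted p = 8.14e-08; adjusted p = 0.189 with an estimated correlation). They included P4ha3 and P4hb, subunits of prolyl hydroxylase, at 3.67 and 1.39, and the collagen chaperone Serpinh1 at 1.83. Among 31 proteoglycans and matrix glycoproteins 20 rose and 9 fell, 20 and 9 adjusted over the list alone, with Postn at 6.10, Fbn2 at 6.04 and Tnc at 3.63 (camera adjusted p = 1.31e-06; adjusted p = 0.189 with an estimated correlation). Of 24 matrix-degrading enzymes and inhibitors 17 rose and 6 fell, 17 and 6 adjusted over the list alone, with the metalloproteinases Mmp19 at 2.57 and Mmp14 at 2.06 (camera adjusted p = 0.00142; adjusted p = 0.189 with an estimated correlation). Secretory pathway genes rose in 24 of 30 cases and fell in 2, also adjusted over the list alone, among them Kdelr2 at 1.68 and the translocon gene Sec61a1 at 1.37 (camera adjusted p = 1.08e-07; adjusted p = 0.332 with an estimated correlation). Ribosome biogenesis genes rose in 25 of 38 cases and fell in 2, Npm1 by 1.18 and Gnl3 by 1.21 among the risers (camera adjusted p = 0.0078; adjusted p = 0.805 with an estimated correlation). Cytosolic ribosomal protein genes rose in 36 of 78 cases and fell in 2 (camera adjusted p = 0.0169; adjusted p = 0.881 with an estimated correlation). Here and in the later comparisons, counts of these genes are uncertain where reads also match a pseudogene.

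Of 26 macrophage markers 20 rose and 1 fell, also adjusted over the list alone, with Cd68 at 2.34, Trem2 at 2.37 and Tyrobp at 2.02 (camera adjusted p = 4.90e-09; adjusted p = 0.216 with an estimated correlation). Neutrophil markers rose in 6 of 10 cases, with the receptor Csf3r at 4.0 and S100a9 at 5.48 (camera adjusted p = 0.00612; adjusted p = 0.42 with an estimated correlation). Inflammatory cytokines and chemokines rose in 22 of 29 cases and fell in 2, with Lif at 2.55 and Osm at 2.94 (camera adjusted p = 0.000615; adjusted p = 0.332 with an estimated correlation). Regenerating muscle markers rose in 12 of 16 cases (camera adjusted p = 0.0016; adjusted p = 0.602 with an estimated correlation). Of 28 skeletal muscle fibre markers 25 fell and 2 rose, with Tnni2 at -6.15 (camera adjusted p = 2e-05; adjusted p = 0.644 with an estimated correlation). Their share of all counts was 6.32% ± 2.08 at day 0 and 0.184% ± 0.107 at day 7 (SD, n = 4). All 7 mitochondrially encoded mRNAs fell, mt-Nd2 by 3.27 and mt-Nd4 by 2.53 on the log2 scale (camera adjusted p = 4.90e-09; adjusted p = 0.189 with an estimated correlation), and 67 of 73 nuclear oxidative phosphorylation genes fell and 2 rose (camera adjusted p = 6.83e-09; adjusted p = 0.637 with an estimated correlation). All 15 adipocyte markers fell, with Scd1 at -3.03 and Dgat2 at -2.89 (camera adjusted p = 4.68e-06; adjusted p = 0.332 with an estimated correlation). Endothelial markers fell in 13 of 20 cases (camera adjusted p = 0.00804; adjusted p = 0.637 with an estimated correlation), and Schwann cell and nerve markers fell in 12 of 18 and rose in 4 (camera adjusted p = 0.0282; adjusted p = 0.332 with an estimated correlation). Keratinocyte markers fell in 10 of 14 cases (camera adjusted p = 0.051).

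Tenogenic genes fell in 8 of 16 cases and rose in 1, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.00831; adjusted p = 0.378 with an estimated correlation). Fmod and Comp, which bind collagen fibrils, stood at -1.94 and -2.22 and Cilp2 at -4.18, while Scx at 0.39 did not pass (edgeR adjusted p = 0.214). TGF-beta and BMP pathway genes fell in 19 of 33 cases and rose in 6, with Gdf5 at -2.43, Bmp2 at -2.92 and Smad3 at -1.27 (camera adjusted p = 0.00168; adjusted p = 0.378 with an estimated correlation). FoxO-responsive genes, which insulin-like signals repress, fell in 13 of 20 cases and rose in 3 (camera adjusted p = 0.000451; adjusted p = 0.189 with an estimated correlation), with Bcl6 at -2.12, Foxo4 at -1.90 and Txnip at -2.0. IGF signalling components went both ways, 7 up and 9 down of 18, the same adjusted over the list alone (camera adjusted p = 0.71). The protease Pappa, which frees IGF from its binding proteins, rose by 3.38 and Igf2r by 1.01, Igfbp6 stood at -2.52, and Igf1r itself fell by 0.35 (edgeR adjusted p = 0.000865). The chondrocyte markers rose in 4 and fell in 6 of 17 cases (camera adjusted p = 0.703), with Acan at 4.52 and Chad at -5.31.

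Several lists moved in both directions without a call by camera at day 7 against day 0. Of 22 glycolysis genes 4 rose and 11 fell (adjusted p = 0.43), of 23 integrated stress response genes 13 rose and 5 fell (0.31), and of 29 genes of amino acid transport and translation factors 15 rose and 5 fell (0.265). Of 25 autophagy and lysosome genes 11 rose and 10 fell (0.703), of 23 immediate early genes 6 rose and 7 fell (0.68), and of 21 cholesterol synthesis genes 9 rose and 1 fell (0.137). Basement membrane genes rose in 6 and fell in 9 of 20 cases (0.703), pericyte and smooth muscle markers rose in 5 and fell in 7 of 15 (0.703), and progenitor and paratenon fibroblast markers rose in 8 and fell in 9 of 21 (0.685). T and NK cell markers rose in 8 and fell in 2 of 20 cases (0.286), B and plasma cell markers rose in 1 and fell in 3 of 12 (0.81), mast cell markers rose in 2 and fell in 2 of 10 (0.812), bone cell markers rose in 6 and fell in 3 of 12 (0.644), and 0 of 7 erythroid markers passed with edgeR (0.812).

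**Figure D3:**
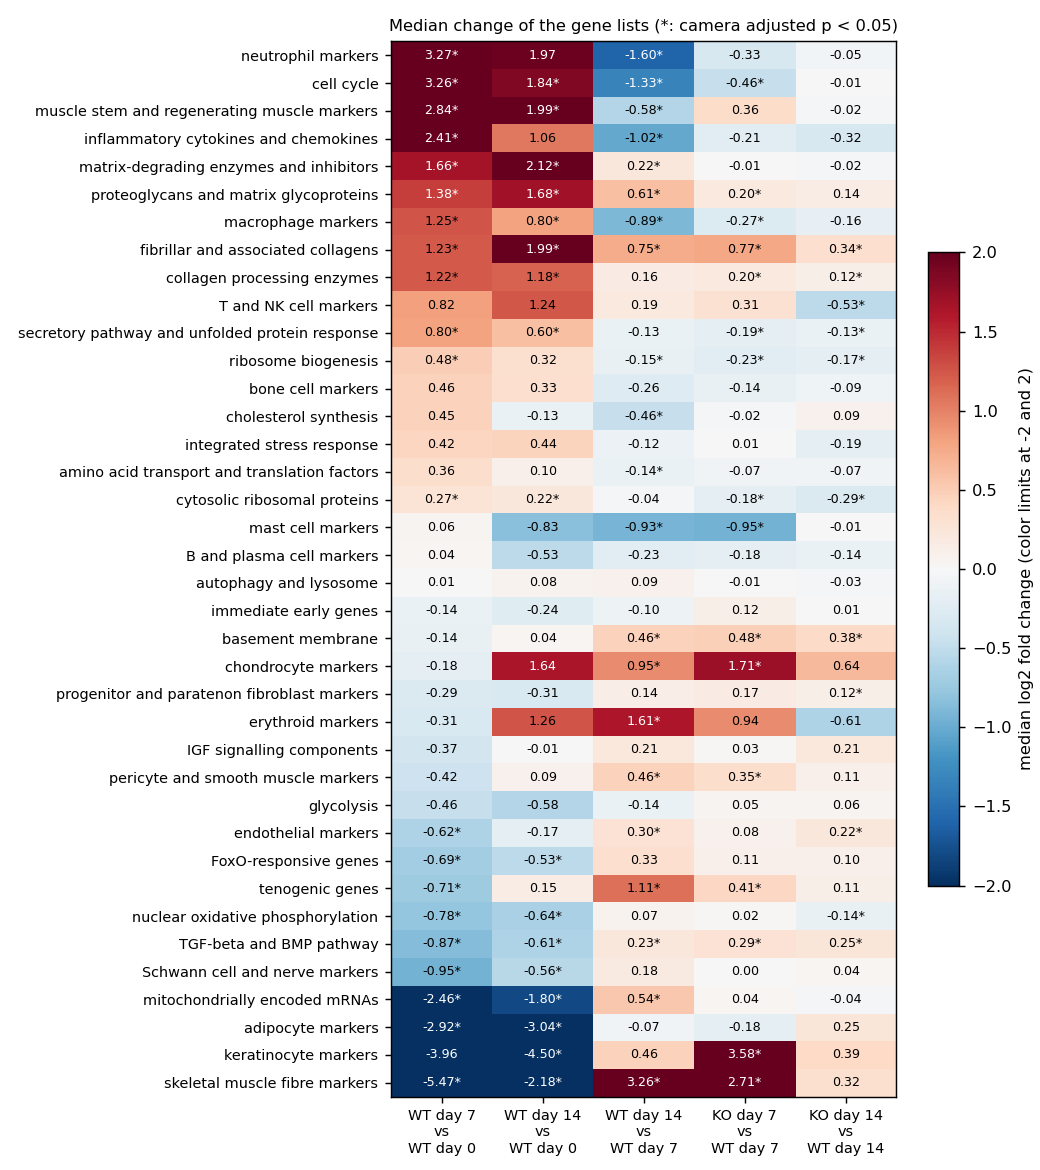
Median log2 fold change of the members of each of the 38 gene lists (rows) in 5 comparisons (columns), as numbers and colors, with an asterisk where camera with its preset correlation passed. Cell cycle genes read 3.26 at WT day 7 against day 0 and -1.33 at WT day 14 against WT day 7.

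By day 14, WT tendon differed from day 0 in 10268 genes, 5306 higher and 4962 lower. C1qtnf3 rose by 8.34 ± 0.40 on the log2 scale and Cthrc1 by 8.20 ± 0.24 (SE, n = 4 per group), the kallikrein Klk1 by 7.58, the collagenase Mmp13 by 7.52 and Prss35 by 7.05. The fast myosin Myh4 stood at -6.59, Odf3l2 at -7.65 and the serum albumin gene Alb at -6.19. Of 20 collagens 17 rose and 0 fell, as adjusted over the list alone, with Col3a1 at 2.91, Col8a1 at 4.87 and Col5a2 at 2.44 (camera adjusted p = 5.85e-17). This list, the collagen processing enzymes (22 of 26 up, 3 down, camera adjusted p = 5.22e-15, P4ha3 at 3.93), the proteoglycans and matrix glycoproteins (21 of 31 up, 8 down, camera adjusted p = 5.22e-15) and the matrix-degrading enzymes (18 of 24 up, 4 down, camera adjusted p = 1.08e-07) were the 4 that also passed with an estimated correlation, at adjusted p = 0.0477, 0.0477, 0.00785 and 0.00785. The other 13 of 17 list calls were lost with an estimated correlation. Of these, cell cycle genes rose in 42 of 44 cases, with Cdk1 at 3.18 (camera adjusted p = 8.08e-18; adjusted p = 0.307 with an estimated correlation). All 15 adipocyte markers fell again (camera adjusted p = 1.87e-09; adjusted p = 0.209 with an estimated correlation), as did the 7 mitochondrial mRNAs (camera adjusted p = 4.45e-09; adjusted p = 0.181 with an estimated correlation). FoxO-responsive genes fell in 13 of 20 cases and rose in 3 (camera adjusted p = 0.00154; adjusted p = 0.181 with an estimated correlation), with Bcl6 at -2.11. Igf1, the receptor's ligand, rose by 1.68 ± 0.17, Pappa by 3.14, Tnmd, a marker of mature tenocytes, by 3.02 and Scx by 1.57, while Igf1r fell by 0.47 (edgeR adjusted p = 7.86e-05).

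Between day 7 and day 14 in WT, camera with its preset correlation placed 12 lists higher and 9 lower, and all 21 calls were lost with an estimated correlation. Of 44 cell cycle genes 43 fell, 44 adjusted over the list alone, with Plk1 at -1.78 and Mcm4 at -1.01 (camera adjusted p = 5.71e-32; adjusted p = 0.33 with an estimated correlation). Of 26 macrophage markers 20 fell and 1 rose, with Ccr2 at -1.96 and Cd68 at -0.93 (camera adjusted p = 4.35e-11; adjusted p = 0.33 with an estimated correlation). Neutrophil markers fell in 7 of 10 cases, with Csf3r at -2.03 (camera adjusted p = 0.000265; adjusted p = 0.368 with an estimated correlation), and cytokines and chemokines in 13 of 29, with the arginine-cleaving Arg1 at -4.45, Osm at -1.88 and Lif at -1.24 (camera adjusted p = 2.31e-05; adjusted p = 0.368 with an estimated correlation). Il1b stood at -2.60, Mmp9 at -3.37 and Hmga2, a chromatin protein of growing tissue, at -2.83. Mast cell markers fell in 5 of 10 cases (camera adjusted p = 0.00463; adjusted p = 0.531 with an estimated correlation) and cholesterol synthesis genes in 7 of 21, with Mvk at -0.55 and Lss at -0.75 (camera adjusted p = 0.000498; adjusted p = 0.545 with an estimated correlation). Tenogenic genes rose in 12 of 16 cases and fell in 1, the same adjusted over the list alone, with Tnmd at 2.80, Fmod at 1.45, Kera at 1.92 and Cilp2 at 2.88 (camera adjusted p = 4.35e-11; adjusted p = 0.0568 with an estimated correlation). Scx rose by 1.18. Collagens rose in 13 of 20 cases, 16 adjusted over the list alone, with Col15a1 at 1.28 (camera adjusted p = 5.02e-07; adjusted p = 0.368 with an estimated correlation), and chondrocyte markers in 7 of 17, with Col2a1 at 4.29 (camera adjusted p = 0.00231; adjusted p = 0.531 with an estimated correlation). Timp2 and Mmp2 rose by 1.27 and 1.10, and Mstn, a brake on muscle growth, by 4.28. Muscle fibre markers rose in 25 of 28 cases, with Myl2 at 6.23, Myh2 at 5.67 and Mb at 4.76 (camera adjusted p = 7.24e-09; adjusted p = 0.531 with an estimated correlation), and their share of counts was 0.184% ± 0.107 at day 7 and 1.35% ± 1.09 at day 14 (SD, n = 4). Igfbp6 rose by 1.34 and Stc2 by 1.49, and Pappa2 stood at -2.89. In total 3031 genes rose and 2714 fell (edgeR). With the muscle score as a covariate 3203 genes passed.

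**Figure D4:**
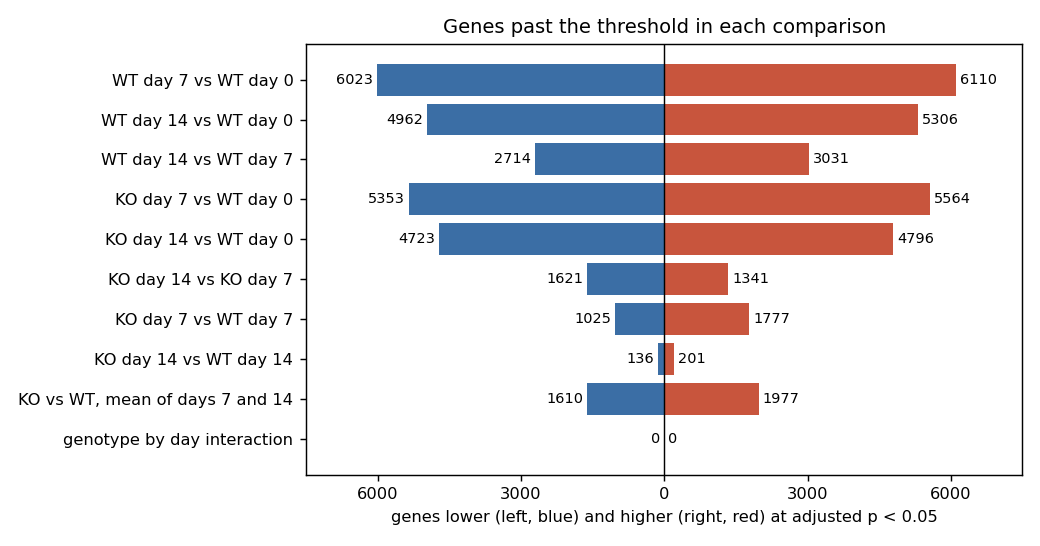
Number of genes higher (right, red) and lower (left, blue) at adjusted p below 0.05 (edgeR) in each of the 10 comparisons. The WT day 7 against WT day 0 bars are the longest, at 6110 and 6023, and the interaction has 0.

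Against WT day 0, KO tendon differed in 10917 genes at day 7 (5564 higher, 5353 lower) and in 9519 at day 14 (4796 higher, 4723 lower; edgeR). Because these groups differ in genotype, tamoxifen and growth stimulus together, the comparisons do not separate them. Scx rose by 4.26 and 5.02 and Igf1r fell by 0.29 (edgeR adjusted p = 0.00495) and 0.24 (adjusted p = 0.0189). The day 14 call of Igf1r was lost without WT day 0 replicate 2, KO day 14 replicate 1 or KO day 14 replicate 4. From KO day 7 to KO day 14, 1341 genes rose and 1621 fell, while Igf1r at 0.05 (adjusted p = 0.741) and Scx at 0.76 (adjusted p = 0.0637) did not pass. Without KO day 14 replicate 1 this total of 2962 was 1693, and without KO day 7 replicate 2 it was 1885.

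At day 7 of growth, camera with its preset correlation placed 10 lists higher in KO than in WT, among them collagens, chondrocyte markers and muscle fibre markers, and 6 lower, among them cell cycle genes and mast cell markers. All 16 of these calls were lost with an estimated correlation. Scx was higher by 3.87 ± 0.30 on the log2 scale and Bop1 by 1.80 ± 0.22 (SE, n = 4 per group). Fabp2, of gut fatty acid uptake, was higher by 8.38 ± 0.51, the histidine-degrading Hal by 7.87 ± 1.15 and the pseudogene Rpl3-ps1 by 6.04 ± 0.29. The cartilage collagen Col2a1 was higher by 5.99, Susd5 by 4.50, Meltf by 4.45, Myh2 by 4.30 and Ankrd2 by 4.13. Rpl3, the parent gene of that pseudogene, stood at -2.40, Ang at -2.30, Rpl29 at -2.08, Naip5 at -1.98, Hmgn2 at -1.74, Dynlt1b at -1.58 and Steap1 at -1.45. Counts of Rpl3 and Rpl3-ps1 are uncertain, since reads of near-identical copies can be split between them. In total 1777 genes were higher and 1025 lower (edgeR), 562 and 143 of them at least 2-fold.

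Of 20 collagens 14 were higher and 0 lower, 15 adjusted over the list alone, with Col6a2 at 1.04, Col6a1 at 0.88 and Col15a1 at 1.25 (camera adjusted p = 9.41e-11; adjusted p = 0.408 with an estimated correlation). The list's share of all counts was 10.9% ± 0.573 in WT and 15.6% ± 0.900 in KO (SD, n = 4), and no KO library overlapped a WT library. Tenogenic genes were higher in 6 of 16 cases, with Comp at 1.27, Fmod at 1.01 and Cilp2 at 1.79 beside Scx (camera adjusted p = 2.20e-05; adjusted p = 0.408 with an estimated correlation). Scx, which carries the recombinase in KO mice, is 1 of these 6, and the list was not tested without it. Basement membrane genes were higher in 9 of 20 cases, with Hspg2 at 0.93 and Col4a2 at 0.83 (camera adjusted p = 6.34e-05; adjusted p = 0.56 with an estimated correlation), and TGF-beta and BMP pathway genes in 10 of 33, with Gdf5 at 1.23, Ltbp3 at 0.72 and Tgfb2 at 0.63 (camera adjusted p = 0.000625; adjusted p = 0.56 with an estimated correlation). Collagen processing enzymes were higher in 7 and lower in 1 of 26 cases, the lower one being the crosslinking enzyme Lox at -0.55 (camera adjusted p = 0.0106; adjusted p = 0.744 with an estimated correlation). Proteoglycans and matrix glycoproteins were higher in 7 and lower in 1 of 31 cases, with Prelp at 1.24 and Fn1 at 0.64 (camera adjusted p = 0.0122; adjusted p = 0.582 with an estimated correlation). Timp2 at 0.88 and Mmp14 at 0.59 also passed. Chondrocyte markers were higher in 8 of 17 cases, 11 adjusted over the list alone, with Acan at 1.71 and Sox5 at 0.79 (camera adjusted p = 1.30e-06; adjusted p = 0.408 with an estimated correlation), and pericyte and smooth muscle markers in 5 and lower in 1 of 15, with Cspg4 at 1.14 (camera adjusted p = 0.0257; adjusted p = 0.647 with an estimated correlation). The call of Lox was lost without any 1 of 5 libraries (WT replicate 2, 3 or 4, KO replicate 3 or 4; adjusted p up to 0.084). The collagen processing list was lost without WT day 7 replicate 1 (camera adjusted p = 0.0801), the proteoglycans without KO day 7 replicate 1 (0.0652), and the pericyte list without WT day 7 replicate 3 or 4 (0.0561 and 0.187).

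IGF signalling components did not pass as a list in KO against WT at day 7 (3 higher, 1 lower of 18, with 4 and 1 adjusted over the list alone; camera adjusted p = 0.613). Igf1 stood at -0.52 (edgeR adjusted p = 0.0389), Igf2 higher by 1.72 (adjusted p = 0.0236) and Igfbp6 higher by 0.97, while Igf1r at 0.06 did not pass. FoxO-responsive genes passed in 2 upward and 1 downward case of 20, with Foxo4 at 0.49 and Pik3ip1 at 0.77 (camera adjusted p = 0.254). Sesn2 and Atf5, of the integrated stress response, were higher by 1.09 and 0.62, in a list that did not pass (camera adjusted p = 0.762). Cell cycle genes were lower in 6 of 44 cases, also adjusted over the list alone, with Mcm4 at -0.42 and Rrm1 at -0.45 (camera adjusted p = 7.45e-08; adjusted p = 0.744 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 6 and higher in 1 of 78 cases (camera adjusted p = 7.48e-07; adjusted p = 0.769 with an estimated correlation), ribosome biogenesis genes lower in 3 and higher in 1 of 38, the higher one being Bop1 (camera adjusted p = 0.00322; adjusted p = 0.811 with an estimated correlation), and secretory pathway genes lower in 6 and higher in 2 of 30 (camera adjusted p = 0.00438; adjusted p = 0.769 with an estimated correlation). Macrophage markers were lower in 2 of 26 cases, Tyrobp at -0.37 and Aif1 at -0.51 (camera adjusted p = 0.00337; adjusted p = 0.744 with an estimated correlation), and mast cell markers in 5 of 10, 9 adjusted over the list alone, with Fcer1a at -2.32 and Cpa3 at -1.46 (camera adjusted p = 2.76e-06; adjusted p = 0.433 with an estimated correlation). The alarmin Il33 stood at -1.11, and the immediate early genes Jund and Klf4 were higher by 0.95 and 0.99. Several of these calls were close to the threshold and were lost when 1 of the 8 libraries was left out. Leaving out any 1 of 6 cost the call of Igf1 (WT replicate 1, 2 or 4, KO replicate 1, 2 or 3; edgeR adjusted p up to 0.134) and of Aif1 (WT replicate 2, 3 or 4, KO replicate 1, 2 or 3; up to 0.0923). For Rrm1 it was 5 (WT replicate 1 or 2, KO replicate 2, 3 or 4; up to 0.0981), and 4 for Igf2 (WT replicate 2 or 3, KO replicate 3 or 4; up to 0.097). It was also 4 for Tyrobp and Pik3ip1 (WT replicate 2, 3 or 4, KO replicate 4; up to 0.0986 and 0.0743), and 3 for Mcm4 (WT replicate 2, KO replicate 3 or 4; up to 0.082). Foxo4 and Cpa3 lost theirs without KO replicate 4 (0.0651 and 0.0519), and the ribosome biogenesis list without WT replicate 2 (camera adjusted p = 0.0924).

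Muscle fibre markers were higher in KO at day 7 in 22 of 28 cases, with Pvalb at 3.88 and Mb at 2.78 (camera adjusted p = 4.35e-13; adjusted p = 0.56 with an estimated correlation), and held 0.184% ± 0.107 of counts in WT and 1.06% ± 0.408 in KO (SD, n = 4). Keratinocyte markers were higher in 6 of 14 cases, with Perp at 3.93 and Krt1 at 6.97 (camera adjusted p = 0.0396; adjusted p = 0.811 with an estimated correlation). Without KO day 7 replicate 2, which held 0.0858% keratinocyte counts, the camera adjusted p of that list was 0.732, and without WT day 7 replicate 1, 2 or 3 it was 0.0855, 0.0828 and 0.0857. The total of 2802 genes was 1102 with the muscle score as a covariate, 1440 without WT day 7 replicate 2 and 1504 without KO day 7 replicate 4. Of 114 genes past the threshold that the naming rule takes at day 7, 49 lost the call without at least 1 library and 65 did not. Among the 49 were Krt1 (without WT replicate 1, 2 or 3 or KO replicate 2; edgeR adjusted p up to 0.568), Perp (without WT or KO replicate 2; up to 0.0689) and Mb (without WT or KO replicate 4; up to 0.0623).

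**Figure D5:**
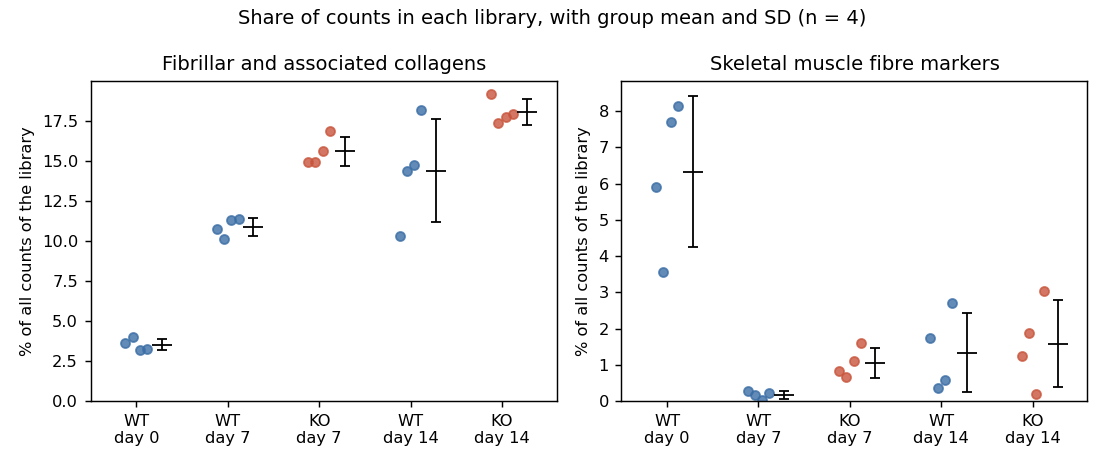
Share of all counts of each library (points, WT blue and KO red) taken by the 20 fibrillar and associated collagens (left) and the 28 skeletal muscle fibre markers (right), in percent, with the group mean and SD (bars, n = 4). Collagen shares at day 7 are 10.9% in WT and 15.6% in KO, and muscle shares 0.184% and 1.06%.

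At day 14 the genotypes differed in 337 genes, 201 higher and 136 lower in KO (edgeR), and several of the largest differences were those of day 7. Hal was higher by 8.11 ± 1.22 on the log2 scale, Rpl3-ps1 by 5.47 ± 0.29, Scx by 3.45 ± 0.30 and Bop1 by 2.40 ± 0.23 (SE, n = 4 per group). Fabp2 had 1765 counts in KO and 1 in WT, a ratio of 2229 (95% counting interval 400 to 88100). The adenylyl cyclase Adcy1 was higher by 1.78, Epha5 by 1.76 and Opcml by 1.56. Mgp, which keeps soft tissue from calcifying, was lower, with 299 CPM in KO and 978 in WT (-1.71 ± 0.17 on the log2 scale). Dynlt1b stood at -1.75, Chst5 at -1.67, Rpl3 at -1.42, Hmgn2 at -1.41, Cisd3 at -1.24 and Kcnk1 at -1.13. Camera with its preset correlation placed 6 lists higher and 5 lower, and all 11 calls were lost with an estimated correlation. Of 20 collagens 2 were higher, 5 adjusted over the list alone, Col5a1 at 0.73 and Col15a1 at 0.85 (camera adjusted p = 1.21e-06; adjusted p = 0.679 with an estimated correlation). The basement membrane list was higher (camera adjusted p = 1.25e-06), with 0 of 20 genes past in edgeR, as were endothelial and progenitor lists. Oxidative phosphorylation, ribosome biogenesis, secretory pathway and T and NK cell lists were lower. TGF-beta and BMP pathway genes were higher in 2 of 33 cases, Tgfb2 at 0.61 and Gdf7 at 2.14 (camera adjusted p = 0.00155; adjusted p = 0.679 with an estimated correlation), and collagen processing enzymes in 2 of 26, with Loxl2 at 0.52 (camera adjusted p = 0.0196; adjusted p = 0.854 with an estimated correlation). The joint lubricant Prg4 at 1.17, Timp2 at 0.56 and Sesn2 at 0.87 also passed, as did Ctsd at -0.45. Of 78 cytosolic ribosomal protein genes 4 were lower, 46 adjusted over the list alone, with Rpl35a at -1.09 (camera adjusted p = 2.28e-18; adjusted p = 0.679 with an estimated correlation). Some of them had few counts, such as Rpl13 at 11.5 CPM in KO and 15.6 in WT. Rpl3 varied widely in KO, at 19.9 ± 12.2 CPM against 53.4 ± 4.13 in WT (SD, n = 4). Of 18 IGF signalling components 0 passed in edgeR (0 adjusted over the list alone; camera adjusted p = 0.052), with Igf2r at 0.31 (edgeR adjusted p = 0.0897).

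The day 14 collagen share was 14.4% ± 3.21 in WT and 18.0% ± 0.793 in KO (SD, n = 4), and the muscle share 1.35% ± 1.09 and 1.59% ± 1.20. The count of 337 moved when 1 library was left out. It was 152, 170, 184 and 1672 without WT day 14 replicate 1, 2, 3 or 4. Without KO day 14 replicate 1, 2, 3 or 4 it was 176, 198, 167 and 423. A fit to these 8 libraries alone called 86 genes and DESeq2 709. Of 32 genes past the threshold that the naming rule takes at day 14, 19 lost the call without at least 1 library and 13 did not. Of the genes named above, Col15a1 lost it without any 1 of 7 libraries, all but WT replicate 4 (edgeR adjusted p up to 0.16). Col5a1 and Prg4 lost it without any 1 of 6 (up to 0.1 and 0.131), and Chst5, Kcnk1, Loxl2 and Gdf7 without any 1 of 5 (up to 0.128, 0.129, 0.124 and 0.176). Rpl3 and Timp2 lost it without any 1 of 4 (up to 0.0627 and 0.0921), and Tgfb2 and Rpl35a without any 1 of 3 (up to 0.0705 and 0.0721). Epha5 lost it without WT replicate 1 or 2 (up to 0.0617) and Ctsd without WT replicate 3 (0.0549). WT replicate 4 was in none of these sets. The collagen processing list was lost without WT replicate 1 (camera adjusted p = 0.235) or KO replicate 3 (0.076), and the TGF-beta list without KO replicate 3 (0.0818).

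Averaged over both days, 1977 genes were higher and 1610 lower in KO (edgeR). Ctse, a protease, was higher by 3.09 ± 0.39 and the Wnt inhibitor Frzb by 2.41 ± 0.30 (SE, n = 8 libraries per genotype), beside Fabp2, Hal, Rpl3-ps1, Scx at 3.66 and Bop1 at 2.10. Rpl3 stood at -1.91, Dynlt1b at -1.66, Hmgn2 at -1.58 and Morf4l1, a chromatin protein, at -0.86 ± 0.05. Of 20 collagens 15 were higher, 16 adjusted over the list alone, with Col15a1 at 1.05 and Col5a1 at 0.85 (camera adjusted p = 2.26e-11; adjusted p = 0.495 with an estimated correlation). Muscle fibre markers were higher in 6 of 28 cases, 24 adjusted over the list alone (camera adjusted p = 4.23e-08; adjusted p = 0.648 with an estimated correlation), and chondrocyte markers in 8 of 17, 12 adjusted over the list alone (camera adjusted p = 4.22e-05; adjusted p = 0.53 with an estimated correlation). TGF-beta and BMP pathway genes were higher in 13 and lower in 2 of 33 cases, with Gdf5 at 0.98 and Tgfb2 at 0.62 (camera adjusted p = 0.000117; adjusted p = 0.53 with an estimated correlation). Of 78 cytosolic ribosomal protein genes 41 were lower and 1 higher, 64 and 1 adjusted over the list alone, with Rps7 at -0.33 (camera adjusted p = 1.07e-13; adjusted p = 0.597 with an estimated correlation). Because counts of these genes are uncertain, this does not by itself show lower ribosomal protein transcripts in KO. Of 38 ribosome biogenesis genes 12 were lower and 1 higher, with Npm1 at -0.37 (camera adjusted p = 0.000732; adjusted p = 0.735 with an estimated correlation). Igf1 stood at -0.47 (edgeR adjusted p = 0.00884), Igfbp5 and Igfbp6 were higher by 0.50 and 0.62, and Sesn2 by 0.98. Prelp at 0.99, Comp at 0.99, Timp2 at 0.72 and Srebf2 at 0.51 were higher, and Tyrobp stood at -0.39. Igf1r at 0.15 did not pass (edgeR adjusted p = 0.0822), and did pass without WT day 14 replicate 4. With the muscle score as a covariate 2166 genes passed.

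Whether the KO effect changed between the days was tested by the interaction, and 0 of 18918 genes passed in edgeR, with a smallest adjusted p of 0.129. An unadjusted p below 0.05 was found for 2039 genes, a count that 15 of 100 splits of the libraries reached (the real one included; highest other 6416). Limma-voom called 0 genes and DESeq2 171 (58 higher, 113 lower). The smallest p belonged to genes such as S100b at -1.59 (edgeR adjusted p = 0.129) and Mstn at -2.78 (adjusted p = 0.135). Scx stood at -0.41 (adjusted p = 0.746) and Igf1r at 0.16 (adjusted p = 0.649). The count of 0 was 11 without WT day 7 replicate 1, 5 without KO day 14 replicate 4, 4 without WT day 14 replicate 4, 2 without KO day 7 replicate 1, and 1 each without WT day 7 replicate 4 and WT day 14 replicate 1. Across genes, which are not independent replicates, the log2 KO effects at day 7 and day 14 correlated with Pearson's r of 0.470 and Spearman's rho of 0.420. In 100 draws of swapped labels, 2 including the real one were as large in absolute size (permutation p = 0.02). The other of these draws swapped the genotypes at day 14 only, which gives the same r with the opposite sign by construction. Apart from the real labels, the highest Pearson's r of the draws was 0.256. With no filter on low counts, Pearson's r between the days was lower than with the filter.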

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

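The 5 checks of Bop1 among those of single libraries were chosen only after the result was seen. Among 50 checks of a group of 4 libraries for 1 value far from the others, 3 were past the limit, where chance gives 2.5. KO day 14 replicate 4 had 43.1 M counts, while the others of its group had 36.5 to 37.5 M. KO day 7 replicate 2 had 1150 CPM of Scx, against 557 to 639 in the others of its group. The same library had 0.0858% of its counts on keratinocyte markers, against 0.000946% to 0.00218% in the others.

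For 10 gene lists the KO effect differed between the days by camera's test of the interaction with its preset correlation. None of the 10 passed with an estimated correlation, and edgeR called 0 genes for the interaction (2039 at an unadjusted p below 0.05, which 15 of 100 splits of the libraries reached; limma-voom 0, DESeq2 171). Skeletal muscle fibre markers had a median interaction of -2.44, from 2.71 at day 7 to 0.32 at day 14 (camera adjusted p = 1.52e-15; adjusted p = 0.732 with an estimated correlation). Cell cycle genes had 0.41, from -0.46 to -0.01 (camera adjusted p = 5.41e-11; adjusted p = 0.959 with an estimated correlation), and mast cell markers 1.0, from -0.95 to -0.02 (camera adjusted p = 4.39e-08; adjusted p = 0.732 with an estimated correlation). Chondrocyte markers had -0.81 (camera adjusted p = 0.000127; adjusted p = 0.732 with an estimated correlation), tenogenic genes -0.44 (camera adjusted p = 0.000708; adjusted p = 0.732 with an estimated correlation) and collagens -0.34, from 0.77 to 0.34 (camera adjusted p = 0.00275; adjusted p = 0.959 with an estimated correlation). Keratinocyte markers had -3.28 (camera adjusted p = 0.00538; adjusted p = 0.959 with an estimated correlation), T and NK cell markers -0.70 (camera adjusted p = 0.00538; adjusted p = 0.959 with an estimated correlation), nuclear oxidative phosphorylation genes -0.15 (camera adjusted p = 0.00538; adjusted p = 0.963 with an estimated correlation) and erythroid markers -1.52 (camera adjusted p = 0.00865; adjusted p = 0.959 with an estimated correlation). With the preset correlation, 5 of these calls were lost without single libraries. They were the collagens without WT day 14 replicate 4 (0.077), keratinocyte markers without KO day 7 replicate 2 (0.569), and oxidative phosphorylation without WT day 14 replicate 1 (0.759) or KO day 14 replicate 1 or 3 (0.0665 and 0.204). T and NK cell markers were lost without KO day 7 replicate 4 (0.167), WT day 14 replicate 4 (0.0877) or KO day 14 replicate 2 (0.0667). Erythroid markers were lost without KO day 7 replicate 2 or 4 (0.08 and 0.0613), WT day 14 replicate 1 (0.174) or KO day 14 replicate 1 (0.0665). With the muscle score as a covariate the oxidative phosphorylation list passed in the opposite direction (camera adjusted p = 0.0111).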

How the results depend on the processing

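No alternative was chosen after the result was seen. RLE scaling, upper-quartile scaling, both filters, limma-voom and the replicate block moved none of the 10 counts of genes by over 1.5 times. Upper-quartile scaling shifted the balance of directions, with 1523 genes up and 1462 down for KO day 14 against KO day 7 (1341 and 1621 in the main fit). For KO against WT at day 7, 55.3% of its calls were up, against 63.4% in the main fit. With the replicate block, KO against WT called 3141 genes at day 7 and 345 at day 14. Of 40 pairs of same-numbered libraries 14 correlated above 0.1 (from -0.165 to 0.272), and 7 of 20 libraries were closest to their own number. Pairs with different numbers were not set beside them, so this check cannot decide whether the numbers pair the libraries. With the muscle score as a covariate, 6839 genes passed for WT day 7 against day 0, 3203 for WT day 14 against day 7, 1102 for KO against WT at day 7 (837 up, 265 down) and 2166 for the mean KO effect, and the cause was not tested. DESeq2 gave 709 for KO against WT at day 14 and 171 for the interaction, and the cause was not tested. A fit to the compared groups alone gave 86 at day 14, with fewer libraries to estimate the spread. The correlation of KO effects between days was 0.26 without a filter, where genes with few counts enter.

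With an estimated correlation 0 lists passed in 6 of the list comparisons and 4 for WT day 14 against day 0. Leaving out 1 library gave 11411 to 11836 calls for WT day 7 against day 0, 9207 to 10594 for WT day 14 against day 0, 4521 to 5912 for WT day 14 against day 7, 10126 to 10549 for KO day 7 and 8467 to 9081 for KO day 14 against WT day 0, 1693 to 2956 for KO day 14 against KO day 7, 1440 to 2659 for KO against WT at day 7, 152 to 1672 at day 14, 2417 to 5211 for their mean and 0 to 11 for the interaction. The correlation between days was 0.385 to 0.518, Igf1r 0.04 to 0.09 at day 7 and 0.16 to 0.26 at day 14, and Scx 3.57 to 3.98 and 3.15 to 3.59. List calls ranged from 21 to 22, 15 to 18 and 17 to 23 in the WT comparisons, 14 to 19 at day 7, 7 to 17 at day 14, 16 to 19 for the mean and 8 to 17 for the interaction.

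These results turned direction, and the cause was not tested. Igf1r for KO day 14 against KO day 7 was -0.02 without KO day 14 replicate 3 (range -0.02 to 0.08). With the muscle score, nuclear oxidative phosphorylation genes turned for WT day 14 against day 7 (camera adjusted p = 0.0036; 0.187 in the main fit). They also turned for KO against WT at day 7 (2.78e-07; main 0.895) and the interaction (0.0111; main 0.00538). Mitochondrial mRNAs turned for KO against WT at day 7 (0.00974; main 0.895) and the interaction (0.0123). Regenerating muscle markers turned for the same comparisons (1.79e-06, main 0.895, and 4.78e-05). Cell cycle genes turned at day 14 without WT day 14 replicate 3 (camera adjusted p = 0.00799; main 0.956), and over all libraries left out the adjusted p ranged from 0.00786 to 0.753. Of these list results only the oxidative phosphorylation interaction was a call in the main fit. The others had no called direction to lose.

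Of 252 results for single genes named here, a part of those that the naming rule allows, RLE and upper-quartile scaling changed 0 calls. The muscle score ended 24 calls, limma-voom 9, the replicate block 8 and the fit without a filter 6, while DESeq2 added 4. The fit to the compared groups alone ended 20 of 251 and added 1. Leaving out 1 library ended 120 of 2272 such results and added 7. Of 266 list results, RLE scaling ended 1 call, the replicate block ended 1 and added 4, no filter added 14, and the muscle score ended 18 and added 16. Leaving out 1 library ended 78 of 2736 list results and added 93.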

Other observations

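The tests of genes near Scx, of neighbouring genes, of pseudogenes, of the Scx and Bop1 counts and exons and of muscle as a source of the collagens, and the splits of the day 7 libraries, were chosen only after the result was seen. For WT day 14 against day 7, 4 lists of vessel, basement membrane and blood genes passed with camera's preset correlation and none of them with an estimated one. Pericyte and smooth muscle markers rose in 7 of 15 cases and fell in 1, with Higd1b at 1.45 and Rgs5 at 1.14 on the log2 scale (camera adjusted p = 0.0167; adjusted p = 0.519 with an estimated correlation). Endothelial markers rose in 4 of 20 cases, with the vascular phosphatase Ptprb at 0.69 and the transcription factor Erg at 0.64 (camera adjusted p = 0.0143; adjusted p = 0.595 with an estimated correlation). Basement membrane genes rose in 8 of 20 cases and fell in 1, with the laminin chain Lama2 at 1.01 (camera adjusted p = 0.0204; adjusted p = 0.561 with an estimated correlation). Erythroid markers rose in 4 of 7 cases, with Slc4a1 at 2.36 and Hbb-bs at 1.59 (camera adjusted p = 0.0314; adjusted p = 0.617 with an estimated correlation). The basement membrane call was lost without WT day 14 replicate 3 or 4 (0.0755 and 0.166), and the erythroid call without WT day 7 replicate 1 (0.0639) or WT day 14 replicate 1 (0.112). The call of Slc4a1 was lost without WT day 7 replicate 4 or WT day 14 replicate 1 (edgeR adjusted p up to 0.133), and that of Hbb-bs without any WT day 7 library or WT day 14 replicate 1 or 2 (up to 0.215).

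Of 229 genes called in KO against WT at both days, 228 changed in the same direction, 152 up and 76 down, where independent lists would share 18.9 and 7.37. Of the 228, 10 lie within 5 Mb of Scx, among them Scx, Bop1, Psca, Slc16a8, Jrk and Rpl3, against a median of 2 and a highest of 11 in 10000 random sets of tested genes (3 sets as many, permutation p = 3e-04), and without Scx and Bop1 8 of 226 do (median 2, 34 of 10000 sets as many, permutation p = 0.0034), so a linked genome segment that differs between the mouse lines may account for these. Pseudogenes were over-represented, with 28 of 228 and an odds ratio of 3.83 (95% interval 2.46 to 5.76, Fisher's exact p = 1.83e-08), which a split of reads between copies, or sequence differences between lines, could give. Scx and Bop1 CPM moved together over the 8 KO libraries (Pearson's r = 0.93, permutation p = 0.00026; Spearman's rho = 0.93, permutation p = 0.00225; 1 relation computed; r = 0.83 without the 2 farthest libraries; r = 0.90 for deviations from the mean of each day, exact p = 0.00521 over 576 orders within days), as reads of 1 altered transcript at the recombinase allele could give. Their exons share 0 bases in GENCODE vM21, which argues against exon overlap in that annotation. The annotation used for the counts is not given, so an overlap there is not excluded. Outside chromosome 15 the 228 genes formed 51 neighbouring pairs within 1 Mb, against a median of 34 in random sets (2 of 1000 as many) and 34 in as many genes of WT day 14 against day 7, so linked segments may reach beyond Scx, and loss of Igf1r stays open for other genes, since recombinase and deletion come together in every KO library.

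The higher collagen transcripts of KO at day 7 were weighed against muscle RNA and the scaling. The collagen list gained 4.69% of all counts and the muscle fibre list 0.871%, although attached muscle would bring its own abundant transcripts first. With upper-quartile scaling 13 collagens passed upward and with RLE scaling 14, so neither scaling accounts for them. A collagen response to the loss of Igf1r may account for them, as may the recombinase or linked sequence, which the design does not separate.

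At day 7, KO differed from WT along the direction in which WT moved from day 7 to day 14. With separate WT day 7 libraries as baselines the mean correlation across genes was 0.473, larger than in any other of 70 labellings of the 8 day 7 libraries (highest other 0.364, exact p = 0.0143). With the trend in muscle transcripts removed it was 0.451 (highest other 0.301, exact p = 0.0143). Muscle shares did not overlap between the genotypes at day 7, with at most 0.28% in WT and at least 0.667% in KO. Any muscle trend left after the removal would therefore favour the real labelling. The value of 0.451 thus cannot decide whether attached muscle gave the correlation. The KO difference and the WT change both subtract WT day 7 libraries. A feature of that group alone, such as its low muscle share (0.184% of counts), could therefore also make the correlation positive. A KO tendon that is further along the WT time course at day 7 may give this pattern, but genes are not independent replicates and no day between was measured.

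WT day 14 replicate 4 had a collagen share of 18.1%, above the other WT day 14 libraries, and 70.3 CPM of Scx, below all KO libraries. Splits of the libraries into other groups were counted for each comparison. The real grouping gave the most calls for WT day 7 against day 0 (12133 calls, highest other 5; 1 of 35 splits as large). It also did for WT day 14 against day 0 (10268, highest other 2627) and WT day 14 against day 7 (5745, highest other 1517). The same held for KO day 7 (10917, highest other 8) and KO day 14 (9519, highest other 647) against WT day 0. It held too for KO day 14 against KO day 7 (2962, highest other 195) and KO day 7 against WT day 7 (2802, highest other 150). For the mean KO effect the real grouping gave 3587 calls (highest other 933, 1 of 100 splits). Every other of the 35 splits mixes libraries of both groups, so a real difference widens the spread within the mixed groups. Having the most calls therefore does not by itself exclude chance. For KO against WT at day 14 other splits gave more calls than the real one (337 calls, highest other 1017; 3 of 35 splits as large). The split with 1017 calls, several times the real count, points to a structure of the samples. It exchanged WT day 14 replicate 4 with KO day 14 replicate 4, and the split with 500 calls exchanged the same WT library with KO day 14 replicate 3. For the interaction, edgeR called 0 genes (2039 at an unadjusted p below 0.05; limma-voom 0, DESeq2 171), so 100 of 100 splits are as large by construction and the count of 0 cannot be tested this way (highest other 3587). For the 2039 genes chance was not excluded, since 15 of 100 splits gave as many (highest other 6416). Both highest values come from the split that swaps the genotypes at day 14, which turns the interaction into the mean effect, so these splits also hold genotype effects.

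The authors' deposited table, over 13266 genes, has 2878 genes with a false discovery rate below 0.05 for KO against WT at day 7, of which 2466 were called here in the same direction, and 306 at day 14, of which 260 were. For WT day 7 against day 0 the authors' deposited table has 9641. The last comparison of the authors' deposited table, headed as KO day 14 against WT day 7, holds 0 such genes and equals the difference of its genotype effects to within 2e-09.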
